A study of Drosophila melanogaster with 2 samples.

How the data were processed

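Chromatin from whole embryos aged 0 to 24 h of a transgenic line expressing CG32772 fused to eGFP was sheared by sonication, per the labels' protocols, to fragments of 200 to 800 bp, and DNA bound to the fusion protein was precipitated with an antibody against the tag. The labels give 2 biological replicates of 1 group, and no library of another condition was analysed here. Per the labels and the description deposited with each library, peaks were called on the dm6 assembly with an alignment of control DNA as a second input. The aligner, the peak caller and their versions are not given in the sources used here.

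The deposited files are peak lists. Each library has a ranked list of all calls and a shorter thresholded list, and both kinds also exist for the libraries jointly. The joint thresholded list of the stricter kind was the main list, and the other joint list was an alternative. The signal per peak is the authors' value, whose scaling is not stated, and it was used only to rank peaks within a list and to set the libraries' ranks side by side. The deposited score per peak is at least 830 in the thresholded lists. The -log10 q-values and, in the ranked lists, the -log10 irreproducible discovery rates (a measure of how well the ranks of a peak agree between lists) are the authors' and were not tested again. Each of the 4746 main-list peaks was found in the joint ranked list with the same interval, score and signal. No read counts were analysed, so the depth of each library is unknown, and intervals printed for shares of peaks or genes cover counting error only.

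Peaks on the arms 2L, 2R, 3L, 3R, 4, X and Y were used, and 47 main-list peaks on other sequences were left out. All peak ends lay within the lengths of the reference arms. Of the main-list arm peaks, 156 had a signal under 20. Each lay within 267 bp of a stronger main-list summit (median 204 bp), so some sites count more than once, and counting summits within 1 kb once leaves 4177. Gene models were those of Ensembl release 115 on assembly BDGP6.54, without transposable elements, and sequence came from the RefSeq copy of the same assembly. Random placement, exact binomial, Fisher's exact and exact McNemar tests were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, figures were drawn with matplotlib 3.10.9, and the CG32772 protein was translated with Biopython 1.88.

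A promoter was the sequence within 500 bp of an annotated TSS. Each summit was given 1 class, in the order promoter, 5' UTR, 3' UTR, coding exon, non-coding exon, intron and intergenic, and the expected share was the share of bases of that class on the same chromosomes. A gene was bound when a summit lay within 500 bp of any of its TSSs. Gene lists were 33 lists of symbols and 6 name patterns. Of 499 symbols, 7 did not match a protein-coding gene of the annotation. Motifs were searched on both strands in windows of 101 bp at each summit and 500 bp to the right. Sequences of 7 bases were ranked on 2L and 2R, and the 10 with the smallest p were tested on 3L, 3R, 4 and X. The alternatives to these choices were the other joint list, each library's own list, the upper 50% of the main list by signal, summits within 1 kb counted once, other promoter widths, flanks, windows and backgrounds, and other rules of overlap.

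The tests of the report, the gene lists, the motifs, the alternatives other than those said to be added, and the rule for naming genes were set before the data were examined. Named are CG32772, the 15 strongest main-list peaks that overlap a peak of both libraries' own lists (by the protein-coding gene with the nearest TSS), up to 6 bound members by signal of each gene list with an adjusted p under 0.05, up to 2 of every other list, the 10 chosen sequences of 7 bases, and motifs with an adjusted p under 0.05. Mentions outside the rule were chosen after their values were seen: the Zelda, Grainyhead and CAGCTG sites, the tract of G, and all genes first named in the closing section. GC content and the position of summits around start sites were also examined after the main results were seen. Adjusted p-values are by Benjamini and Hochberg within each family of tests.

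The tests were tested on simulated data. With 3000 random positions, 1.43% of summit class tests, 0.714% of chromosome tests and 0.208% of motif tests passed the threshold over 20 runs, and with random sets of the 13968 genes no gene list test did. The simulated positions lacked the GC difference between real summits and flanks, and the simulated genes shared no summits. These rates therefore need not hold for the motif and gene list tests on the real lists. A planted promoter share of 30.6% was estimated at 30.7%, a motif planted in 1% of windows was called in 95.0% of 20 runs, a planted sequence of 7 bases ranked at the top in all 3 runs, and a planted overlap of 50.0% was measured at 50.5%.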

Results

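Binding of CG32772, a Drosophila melanogaster protein tagged with the green fluorescent protein eGFP, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA crosslinked to a protein is recovered with an antibody and located in the genome. Whole embryos of a transgenic fly line, collected over 0 to 24 h of development, were precipitated with an antibody against the tag. The longest annotated CG32772 protein has 520 residues with 8 matches to the spacing of a zinc finger of the Cys2His2 kind, a common DNA-binding fold. There was 1 group with 2 biological replicates, so the comparisons are between the libraries, and between bound and unbound sequence, not between conditions. The values are peak lists without read counts, and the sequencing depth of each library is therefore unknown. The list called from both libraries held 4746 peaks, and 4699 of them on the chromosome arms 2L, 2R, 3L, 3R, 4, X and Y form the main list used here. All positions are on the dm6 assembly.

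The libraries placed binding at largely the same positions. Replicate 1 had 3048 peaks of its own and replicate 2 had 3562, or 1.17 times as many. On the arms, 2382 of 3012 replicate 1 peaks (79.1%) were overlapped by a replicate 2 peak, and 2420 of 3537 replicate 2 peaks (68.4%) by a replicate 1 peak. Peaks placed at random on the same chromosomes were overlapped in 1.52% and 1.30% of cases on average, and the highest shares in 1000 placements were 2.19% and 2.01% (one-sided permutation p = 0.001 each, the smallest these placements can give). The 100 strongest peaks of each library were all present in the other. Over 2382 pairs of overlapping peaks the authors' signal had a Spearman rho of 0.804 (95% interval 0.788 to 0.818) and a Pearson r of 0.784 on the log10 scale. These are correlations across peaks, which are not independent replicates. The summits of a pair lay a median of 16 bp apart. Of the main-list peaks, 2392 (50.9%) were in both libraries' own lists, 471 in that of replicate 1 only, 708 in that of replicate 2 only and 1128 in neither. The last class was weaker, with a median signal of 75.3 against 189 for peaks in both.

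**Figure D1:**
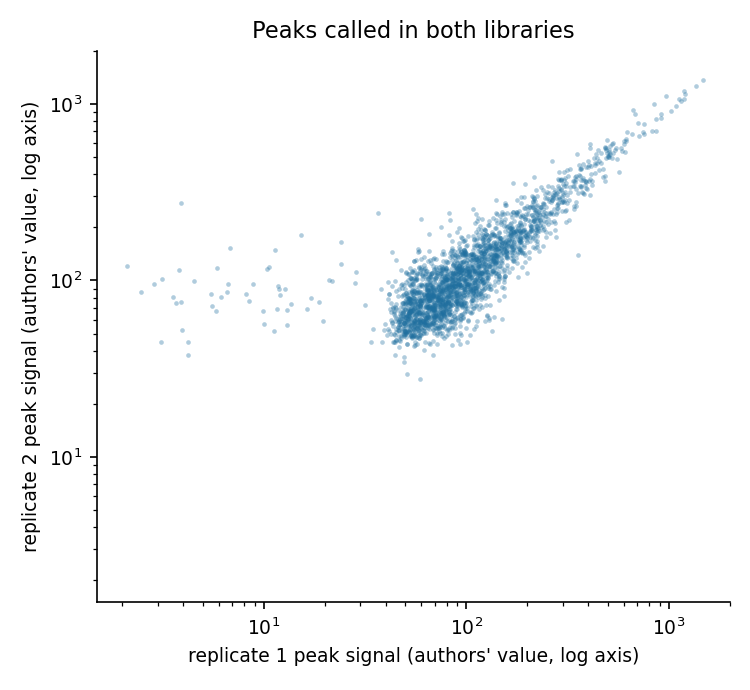
Signal of each of 2382 peak pairs in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), as deposited by the authors. Each point is 1 replicate 1 peak with the strongest replicate 2 peak that overlaps it, and the points rise together (Spearman rho 0.804) apart from weak replicate 1 calls, many with a signal under 20, at the left.

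The strongest site of every thresholded list lay within the tagged gene itself. CG32772 (FBgn0052772) spans positions 4909102 to 4915161 of chromosome X, and the top peak covered positions 4910030 to 4910614, inside an intron and 1262 bp from the nearest of its 2 transcription start sites (TSSs). Its signal was 2941 in the main list, 1483 in replicate 1 and 1361 in replicate 2, rank 1 each time. A peak next to the gene, at positions 4906640 to 4906920, ranked 25 in the main list and in replicate 1, and 22 in replicate 2. The main list held 8 peaks within the gene and 5 kb on either side of it. A tagged transgene can add copies of its own locus, but its extent and copy number are not given in the sources used here. The other calls within 20 kb of the gene were also stronger than most on X, at the median percentile 83.6 in replicate 1 and 74.0 in replicate 2.

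Most of the leading sites present in both libraries were promoter peaks. Of the 15 strongest main-list peaks present in both own lists, 11 had their summit within 500 bp of a TSS, and 8 had as nearest gene one of a divergent pair. All 15 ranked within the first 23 of replicate 1 and within the first 16 of replicate 2. Behind CG32772 came Ugalt, which encodes a UDP-galactose transporter (X, positions 2703719 to 2704063, signal 2593, summit 34 bp from the TSS), CG14100 (3L, 19590444 to 19590783, signal 2362, 95 bp) and CG8320 (2R, 15992319 to 15992664, signal 2310, 78 bp). The peak near CG11050 (2L, 6612544 to 6612892, signal 2243) was intronic. The mitochondrial ribosomal protein gene mRpL41 followed (2R, 15217577 to 15217924, signal 2172, 135 bp). The others at promoters were CG7601, the Polycomb group gene ph-p (X, 2137168 to 2137547, signal 2065), Tcs5, the arginine methyltransferase gene Art3, the chromosomal protein gene Chro, CenG1A and px. The transcription factor gene Adf1 had an intronic peak (2R, 6662884 to 6663231, signal 2028, 786 bp from the TSS). The peak whose nearest TSS was that of CG13323 was the intergenic one of these, 11914 bp away on 2R.

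Binding was concentrated at promoters and nearly absent from coding sequence. Summits within 500 bp of a TSS made up 2011 of 4699 (42.8%, exact 95% interval 41.4 to 44.2%), against 13.5% expected from the sequence of the same chromosomes, a ratio of 3.17. The share was 47.2% in replicate 1 and 45.7% in replicate 2. Coding exons held 51 summits (1.09%) against 13% expected, a ratio of 0.0833 (adjusted exact p = 7.5e-206), with 20 (0.664%, ratio 0.0509) in replicate 1 and 9 (0.254%, ratio 0.0195) in replicate 2, and 2.59% from rank 3001 on. The 3' UTRs held 0.873% against 5.09% (adjusted exact p = 1.0e-57). Intergenic sequence held 15.3% against 27.2% (adjusted exact p = 4.0e-84). Introns held 1817 summits, 38.7% against 39.6% expected, which was not past the threshold (adjusted exact p = 0.252). In each library alone the intron share was below expectation (36.6% and 36.9%, adjusted exact p = 0.00127 and 0.00244), and with promoters narrowed to 200 bp it turned to 1.07 times expectation (adjusted exact p = 3.7e-05). The 5' UTR and non-coding exon shares did not pass (adjusted exact p = 0.0659 and 0.807), although in replicate 1 alone 5' UTRs held fewer summits than expected (0.432% against 0.786%, adjusted exact p = 0.0268). Tests are exact binomial, two-sided, with Benjamini-Hochberg adjustment over 7 classes, and the p for promoters was too small to be given as a number. The promoter share was 63.8% among the 500 strongest peaks and 34.4% from rank 3001 on.

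**Figure D2:**
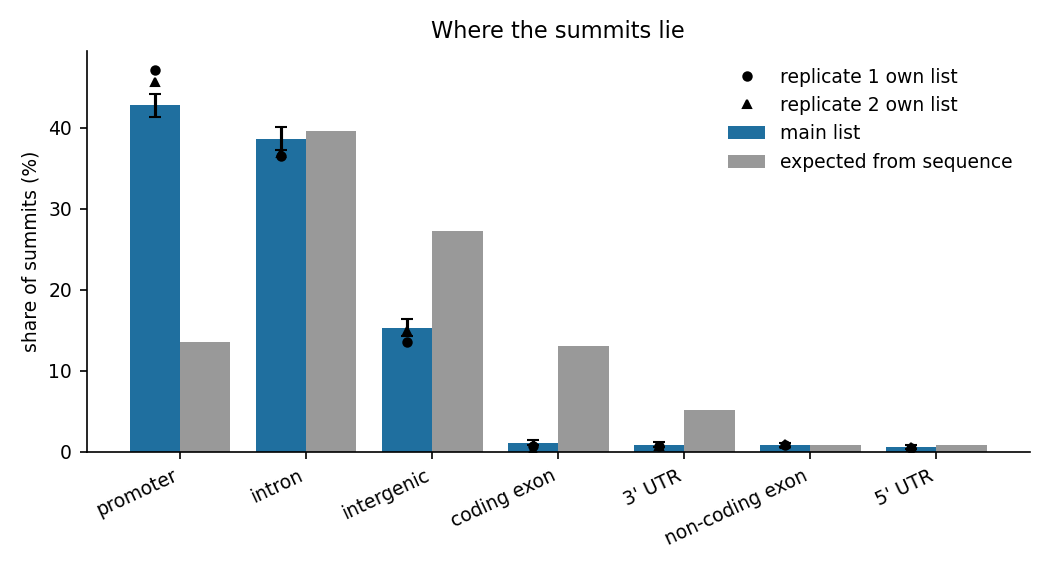
Share of summits (%) in each annotation class for the main list (blue bars, exact 95% binomial intervals) and the share expected from sequence (grey bars), with circles for replicate 1 and triangles for replicate 2. Promoters hold 42.8% of summits against 13.5% expected, and coding exons 1.09% against 13%.

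Promoter summits sat just upstream of the start site. Of 1891 main-list summits within 500 bp of their nearest protein-coding TSS, 78.3% were upstream of it, with a median position of -102 bp. The stretch 50 to 200 bp upstream held 865 of them (45.7%), while the same stretch downstream held 9.36%. The upstream stretch held 49.7% of such summits in replicate 1 and 46.7% in replicate 2. Among random positions it held 17.0%. A summit between start sites that point away from each other is upstream of each. Genes with such a start site within 500 bp were bound more often than others (33.3% against 11.3%), and this was not controlled for here.

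**Figure D3:**
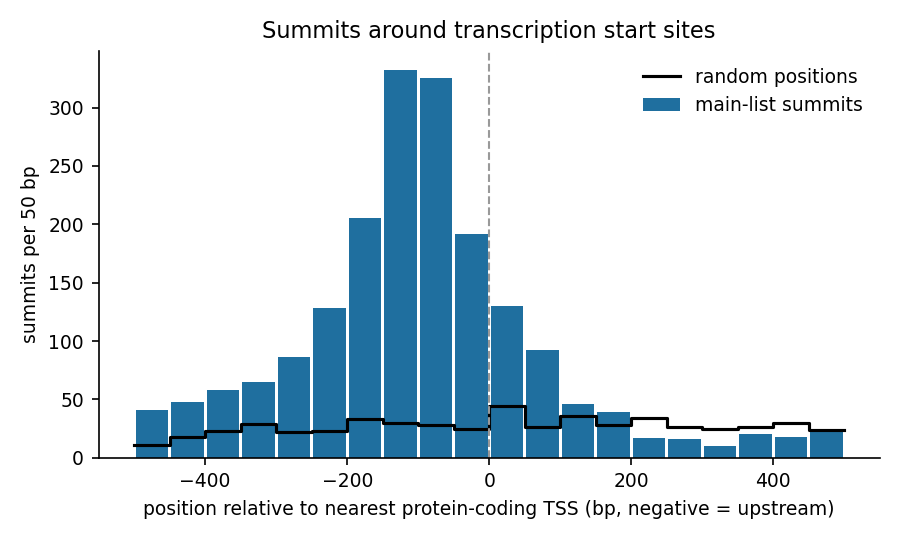
Number of main-list summits per 50 bp (blue bars) by position relative to the nearest protein-coding TSS in bp, negative values upstream, and of as many random genomic positions (black line). Summits gather upstream, with a median of -102 bp.

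Sites were denser on X and missing from chromosome 4. X held 993 main-list peaks, 42.2 per Mb and 1.23 times the number expected from its length (adjusted exact p = 2.6e-12), and its share of peaks was 21.3% in replicate 1 and 21.7% in replicate 2 against 17.1% of the length. By genes X did not stand out: 17.6% of its protein-coding genes had a promoter summit, against 15.1% on 2R and 18.6% on 3L. Among all ranked calls X had 1.04 times the expected number in replicate 1 and 0.999 times in replicate 2. Chromosome 4, a small gene-bearing chromosome with 80 protein-coding genes, held 0 main-list peaks where 46.1 were expected (adjusted exact p = 5.3e-20). Replicate 1 had 0 peaks there and replicate 2 had 2. The repeat-rich Y held 4 against 125.3 expected (adjusted exact p = 1.1e-47), with 1 in replicate 1 and 2 in replicate 2. On 2R the ratio was 0.901 (adjusted exact p = 0.00196), which did not pass in either library alone (0.928 with adjusted exact p = 0.103, and 0.944 with adjusted exact p = 0.138). On 2L, 3L and 3R the main list did not pass, while 3R did in replicate 2 alone (0.91 times expected, adjusted exact p = 0.00569). These are exact binomial tests over 7 arms, and the deposited lists are already restricted by the authors' processing.

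Promoter binding reached 2383 of 13968 protein-coding genes (17.1%), 1797 in replicate 1 and 1966 in replicate 2, with 1507 in both. Of 39 gene lists fixed before the data were examined, 3 were bound more often than other genes and 3 less often (Fisher's exact test, two-sided, Benjamini-Hochberg over all lists), while 10 passed an unadjusted exact p of 0.05. A summit at a divergent promoter can count for both genes.

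Genes of the cytosolic ribosome stood out. Of 91 cytosolic ribosomal protein genes, 43 (47.3%, exact 95% interval 36.7 to 58.0%) had a promoter summit against 16.9% of other genes, an odds ratio of 4.42 (adjusted exact p = 4.5e-10). The count was 36 in replicate 1 and 45 in replicate 2. The strongest were at RpS27 (3R, positions 25247399 to 25247639, signal 515), RpL34b (3R, 9401177 to 9401483, signal 508), RpL32 (3R, 30046216 to 30046471, signal 405), RpL23A (3L, signal 338), RpS28b (X, signal 327) and RpS21 (2L, signal 281), and all 6 were bound in both libraries. Mitochondrial ribosomal protein genes were bound in 21 of 73 cases (28.8%), which did not pass (adjusted exact p = 0.0577). Among genes without a divergent partner, a restriction chosen after the results were seen, 5% of them were bound (adjusted exact p = 0.876). The 21 bound mitochondrial ribosomal protein genes include mRpL41 and mRpS10. The mRpS10 peak (3R, 15229364 to 15229700, signal 1799) is shared with Art3.

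Genes for insulator and promoter-binding proteins, which organise chromatin at domain borders and start sites, were bound in 10 of 20 cases, against 17.0% of other genes (odds ratio 4.88, adjusted exact p = 0.0056). They were Chro (3L, 22878727 to 22879072, signal 1724), Cp190 (3R, 15275232 to 15275528, signal 579), Trl, which encodes the GAGA factor (3L, signal 314), pzg (3L, signal 269), BEAF-32 (2R, signal 196), CTCF (3L, signal 139) and 4 weaker ones. The named 6 were bound in both libraries. The list had 8 bound members in replicate 1 (adjusted exact p = 0.017) and 7 in replicate 2, where it did not pass (adjusted exact p = 0.102).

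Cell cycle and replication genes were bound in 13 of 34 cases (38.2% against 17.0%, odds ratio 3.02, adjusted exact p = 0.0284). The strongest were the E2F partner Dp (2R, 13223296 to 13223518, signal 401), the ribonucleotide reductase gene RnrS (2R, signal 340), the replication licensing gene dup (2R, signal 240), PCNA, the sliding clamp (2R, signal 221), the anaphase activator fzy (2L, signal 203) and the mitotic kinase gene Cdk1 (2L, signal 166), each bound in both libraries. The list had 11 bound members in replicate 1 (adjusted exact p = 0.017) and 10 in replicate 2, where it did not pass (adjusted exact p = 0.119). It did not pass either when summits anywhere in the gene body were counted (38.2% against 22.4%, adjusted exact p = 0.0919). Among genes without a divergent partner, a restriction chosen after the results were seen, 6 of 24 cell cycle genes (25% against 11.2%) and 4 of 11 insulator genes (36.4% against 11.2%) were bound, and neither list passed (adjusted exact p = 0.194 and 0.153).

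Chemosensory, cuticle protein and histone genes were bound less often than other genes. Of 230 chemosensory receptors and odorant-binding proteins 1 was bound, Obp99b (0.435% against 17.3%, adjusted exact p = 5.5e-16). Of 119 cuticle protein genes 2 were bound, Cpr31A and Cpr76Bb (1.68% against 17.2%, adjusted exact p = 1.5e-06). The Cpr31A peak was in the own list of replicate 2 only and the Cpr76Bb peak in neither. Of 116 histone genes 2 were bound, His2Av and His3.3B (1.72% against 17.2%, adjusted exact p = 1.6e-06), which encode histone variants, and the His3.3B peak was in neither library's own list. Most histone genes are copies in a tandem repeat. When the background was limited to genes with a call of any strength, 5 histone genes remained, 2 of them bound, and the list no longer passed (adjusted exact p = 0.623). Among genes without a divergent partner it did not pass either (3.57% against 11.3%, adjusted exact p = 0.705).

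**Figure D4:**
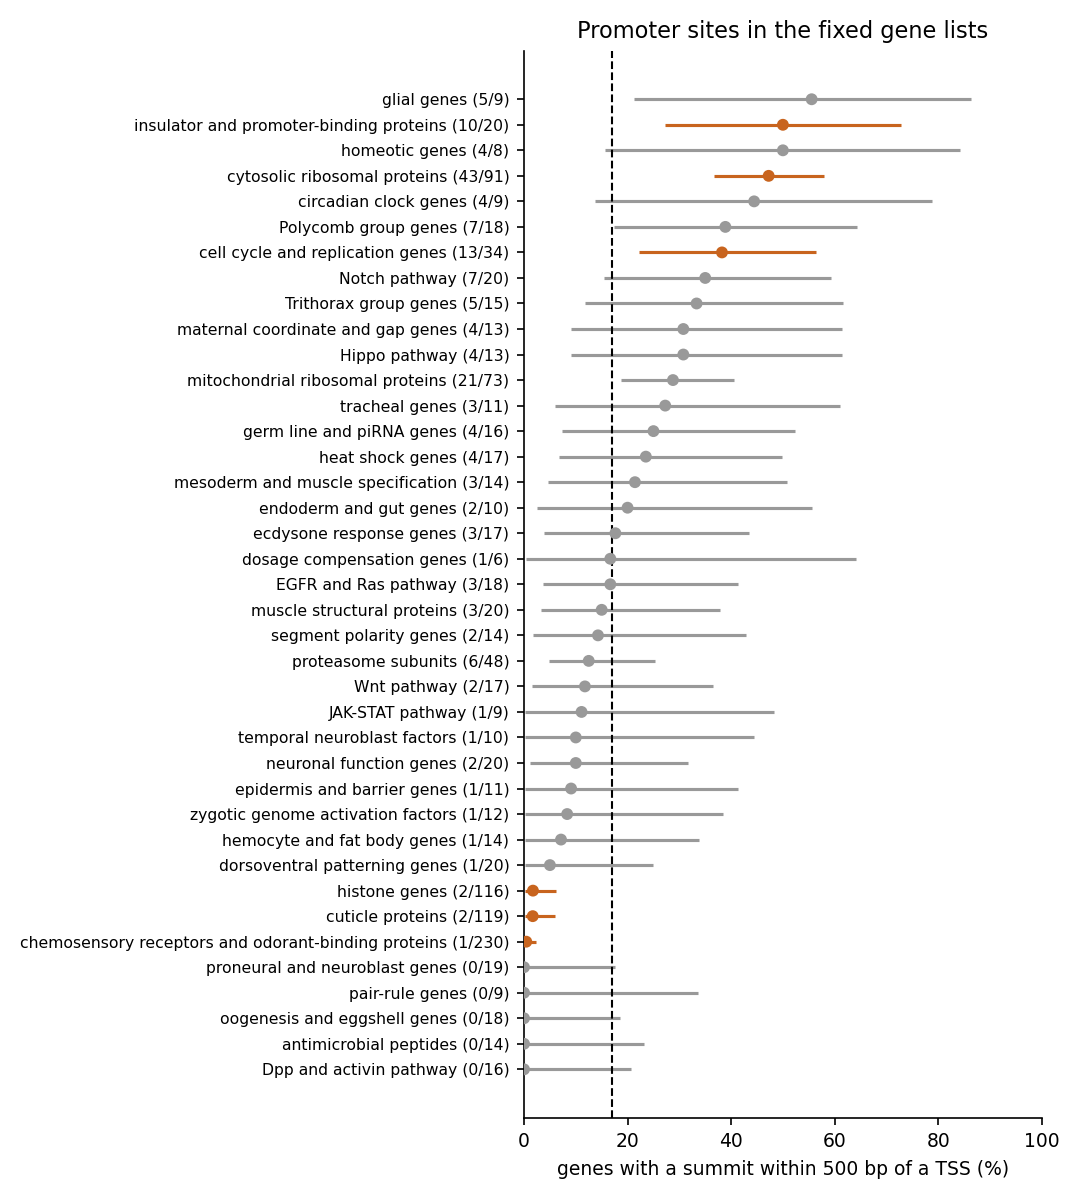
Share of each list's protein-coding genes with a main-list summit within 500 bp of a TSS (%), with exact 95% intervals and the bound and total numbers. Orange marks the 6 lists past an adjusted exact p of 0.05, and the dashed line is the 17.1% of all protein-coding genes.

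No other list passed the adjusted threshold with promoter summits. Counting summits anywhere in the gene body gives long genes more chances of a summit, and gene length was not controlled for. The Polycomb group had 7 of 18 members bound (38.9%, adjusted exact p = 0.101), led by ph-p and the methyltransferase gene E(z) (3L, signal 563), and passed when summits anywhere in the gene body were counted (55.6%, adjusted exact p = 0.0101). The Trithorax group had 5 of 15 (33.3%, adjusted exact p = 0.361), led by the remodeller gene brm (3L, 15982864 to 15983158, signal 1029) and Trl, and passed with gene bodies (53.3%, adjusted exact p = 0.029). Homeotic genes had 4 of 8 in the main list, led by Abd-B and abd-A (adjusted exact p = 0.129), but 1 of 8 in each library alone. Glial genes had 5 of 9 (55.6%, adjusted exact p = 0.0551), led by the blood-brain barrier receptor gene moody (X, signal 707) and Gli, and this list passed with summits up to 1000 bp from a TSS (66.7%, adjusted exact p = 0.0189). Circadian clock genes had 4 of 9 (44.4%, adjusted exact p = 0.18), led by dco and vri.

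Among signalling lists, none passed with promoter summits. The Notch pathway had 7 of 20 members bound (adjusted exact p = 0.181), with E(spl)m3-HLH and neur the strongest. The Hippo pathway had 4 of 13, led by yki and mats. The EGFR and Ras pathway had 3 of 18, led by the ligand gene spi and its antagonist aos. The Wnt pathway had 2 of 17, the kinase gene sgg and nkd. The JAK-STAT pathway had 1 of 9, Stat92E, which was in neither library's own list, and the Dpp and activin pathway had 0 of 16, with 1 in replicate 2. Ecdysone response genes had 3 of 17, led by E23 (2L, signal 614) and Eip75B. With gene bodies counted, the EGFR and Ras list turned from below to above other genes (66.7%, adjusted exact p = 0.000493), and the Hippo (61.5%, adjusted exact p = 0.0108) and ecdysone lists (70.6%, adjusted exact p = 0.000248) also passed. Long genes have more chances of a summit in that count, so these passes may reflect gene length.

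The lists of patterning, tissue and stress genes did not pass either. Maternal coordinate and gap genes had 4 of 13, led by bcd (3R, signal 215) and cad (2L, signal 210), and segment polarity genes had 2 of 14, nkd and mid. Pair-rule genes had 0 of 9, proneural and neuroblast genes 0 of 19, and dorsoventral patterning genes 1 of 20, cact. Zygotic genome activation factors had 1 of 12, Trl, temporal neuroblast factors 1 of 10, Imp, and dosage compensation genes 1 of 6, msl-2. Mesoderm and muscle specification genes had 3 of 14, led by the heart gene tin (3R, signal 420), a list that passed with gene bodies (57.1%, adjusted exact p = 0.0183), and muscle structural protein genes 3 of 20, led by Msp300 and sls. Endoderm and gut genes had 2 of 10, cad and grn, tracheal genes 3 of 11, led by rib and trh, epidermis and barrier genes 1 of 11, sdt, and neuronal function genes 2 of 20, elav (X, signal 678) and Csp. Hemocyte and fat body genes had 1 of 14, ush, and germ line and piRNA genes 4 of 16, led by cuff. Heat shock genes had 4 of 17, led by Hsp27 (3L, 9383779 to 9384060, signal 983) and Hsp83, and proteasome subunit genes 6 of 48, led by Rpn3 and Rpn6. In replicate 1 and replicate 2 alone the counts were 2 and 3 for maternal coordinate and gap genes, 1 and 2 for mesoderm and muscle specification, 1 and 1 for endoderm and gut, 2 and 1 for tracheal, 0 and 0 for epidermis and barrier, 1 and 1 for neuronal function, 0 and 1 for hemocyte and fat body, 3 and 2 for germ line and piRNA, and 0 and 1 for dosage compensation genes. The peaks of msl-2, grn, sdt and Csp were in neither library's own list. Antimicrobial peptide genes had 0 of 14 and oogenesis and eggshell genes 0 of 18. The lists with 0 bound had adjusted exact p of 0.18 to 0.661 and so did not pass.

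Among kinds of gene, protein-coding genes were bound most often. Other genes had a summit in 5.01% of cases against 17.1% (odds ratio 3.90, adjusted exact p = 1.9e-103, Fisher's exact test over 7 biotypes). Transfer RNA genes were bound in 9 of 290 cases (3.10%, adjusted exact p = 4.8e-10, and 1.72% in replicate 1), small nucleolar RNA genes in 9 of 269 (3.35%, adjusted exact p = 4.8e-09), pseudogenes in 4 of 330 (1.21%, adjusted exact p = 1.1e-16), other non-coding RNA genes in 191 of 3289 (5.81%, adjusted exact p = 1.2e-61) and ribosomal RNA genes in 0 of 99 (adjusted exact p = 4.1e-07). Small nuclear RNA genes, with 3 of 32 bound, did not pass (adjusted exact p = 0.613). Within 1000 bp of a TSS, small nucleolar RNA genes were bound in 11.9% of cases, still less often than others (adjusted exact p = 0.0212). Unlike the gene lists, the kinds of gene were not also compared among genes with a call of any strength. The 0 of 99 ribosomal RNA genes thus cannot be told apart from genes at which no call could be made.

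Divergent promoters, where a gene's first TSS lies within 500 bp of that of a gene on the other strand pointing away, were bound about 3 times as often as others. Of 3686 such genes 1226 (33.3%) had a summit, against 1157 of 10282 others (11.3%, odds ratio 3.93, Fisher's exact p = 1.9e-184). The odds ratio was 4.15 in replicate 1 and 3.96 in replicate 2. At such a promoter 1 summit can count for both genes.

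Sequence under the summits was rich in A and T. Of 24 consensus motifs fixed before the data were examined, 7 were more frequent in the window around main-list summits than 500 bp to the right, 4 were less frequent, and 13 did not pass (exact McNemar test, Benjamini-Hochberg over 24). Median GC content was 33.7% at summits against 43.6% in the flank. Base content alone can therefore raise AT-rich motifs and lower GC-richer ones, and it was not controlled for. The largest differences were a tract of A, in 16.0% of summit windows against 6.58% (adjusted exact p = 2.7e-47), and the TATA box TATAAA, in 19.7% against 11.0% (adjusted exact p = 1.5e-30). Both were also more frequent in each library alone, at 13.9% and 17.1% for the A tract and 22.7% and 21.9% for TATAAA at summits. The homeodomain core TAATTA was in 8.94% against 5.85% (adjusted exact p = 1.0e-07), with a ratio of 1.53 that was 1.22 and did not pass at summits more than 500 bp from a TSS (adjusted exact p = 0.16).

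DRE and Motif 1 were rarer but had larger ratios. Unbound promoters were not compared, so these ratios may be those of promoters in general. The DRE sequence TATCGATA, bound by Dref and BEAF-32, was in 1.21% of summit windows against 0.298% of flanks, 4.07 times as often (adjusted exact p = 1.3e-06), with a ratio of 2.29 in replicate 1 (adjusted exact p = 0.0272) and 6.5 in replicate 2 (adjusted exact p = 2.5e-08). Motif 1, GGTCACAC, bound by M1BP, was in 0.958% against 0.234%, a ratio of 4.09 (adjusted exact p = 2.2e-05), with 3.83 in replicate 1 and 2.85 in replicate 2. Among the stronger 50% of peaks it was in 20 summit windows and 1 flank. At summits more than 500 bp from a TSS DRE was in 5 summit windows and 6 flanks (ratio 0.833, adjusted exact p = 1), and Motif 1 in 6 and 1 (ratio 6, adjusted exact p = 0.273). The CTCF consensus AGRKGGC was in 4.94% of summit windows, 1.37 times as often as in flanks (adjusted exact p = 0.00576), but did not pass in either library alone, with ratios of 1.07 and 1.18 (adjusted exact p = 0.768 and 0.234). The Su(Hw) consensus TGCATACTT was in 0.383% against 0.128%, a ratio of 3 (adjusted exact p = 0.0494). Its ratios in the libraries alone were 2.75 and 2.2, which did not pass (adjusted exact p = 0.203 and 0.315). CA repeats (1.51% against 3.83%, adjusted exact p = 1.4e-11), GA repeats (1.53% against 2.23%, adjusted exact p = 0.0354), the E-box CAGGTG of Snail (2.81% against 3.79%, adjusted exact p = 0.0271) and the E-box CACGTG (0.766% against 1.32%, adjusted exact p = 0.0276) were less frequent at summits. The lower GC content of summit windows may by itself account for such losses, which was not tested. At summits more than 500 bp from a TSS CAGGTG turned to 1.19 times its flank frequency and did not pass (adjusted exact p = 0.421). GA repeats had 0.413 times their flank frequency in replicate 1 and 0.6 times in replicate 2. In windows about 2 times as wide neither GA repeats (0.85 times the flank, adjusted exact p = 0.201) nor CACGTG (0.843 times, adjusted exact p = 0.295) passed. CACGTG, at 0.581 times its flank frequency in the main list, had ratios that did not pass in replicate 1 (0.579, adjusted exact p = 0.104), with the flank to the left (0.655, adjusted exact p = 0.0956) and at summits more than 500 bp from a TSS (0.6, adjusted exact p = 0.272). The Zelda site did not pass in the main list (0.511% against 0.575%, adjusted exact p = 0.846) but was less frequent at summits in replicate 2 (0.254% against 0.792%, adjusted exact p = 0.00769), not in replicate 1 (0.398% in both windows). The E-box CAGCTG and a tract of G did not pass in the main list (adjusted exact p = 0.0725 and 0.476), but both were less frequent at summits in each library alone (largest adjusted exact p = 0.0167).

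Without a fixed consensus the same bases emerged. Of 8192 sequences of 7 bases, 290 differed between summit and flank on 2L and 2R. The 10 with the smallest p were AAAAAAA, AAAAAAT, AAAAATT, AAAAATA, AAATAAT, TTAAAAA, AAAAAAC, TAATATA, TAAAAAA and AATAATA, of which 9 hold no G or C. Under the other settings run, 2 to 8 of these were again among the 10 chosen, and no chosen sequence held more than 1 G or C. On 3L, 3R, 4 and X, which were not used to choose them, all 10 were more frequent at summits, by 1.64 to 2.27 times, with adjusted exact p of 3.7e-09 or less. Chromosome 4 held no main-list peak and so added nothing. The lower GC content of summits can by itself raise such sequences on any arm. The test on other arms thus cannot separate a preferred sequence from base content. AAAAAAA was in 21.4% of these summit windows against 10.6% of flanks.

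GC content, examined after the motif results were seen, followed signal. The median over main-list summits was 33.7%, against 43.6% in the flank and 42.6% at random positions, and 3231 of the summits (68.8%) were lower than their own flank. The median difference was -10.9 percentage points in replicate 1 and -9.90 in replicate 2. Among the 100 strongest calls of the ranked lists the median was 27.7% in replicate 1 and 28.2% in replicate 2, and it rose to 49.5% and 47.5% for ranks 5001 to 20000. Over the same span the promoter share went from 68.0% to 15.8% in replicate 1 and the coding exon share from 0 to 18.4%. Ranks from 5001 on lie beyond the length of each library's thresholded list. At ranks 2001 to 3000, within that length, the median GC content was 34.7% in both libraries. Across thresholded peaks the Spearman rho of GC content with signal was -0.264 in replicate 1 and -0.265 in replicate 2.

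**Figure D5:**
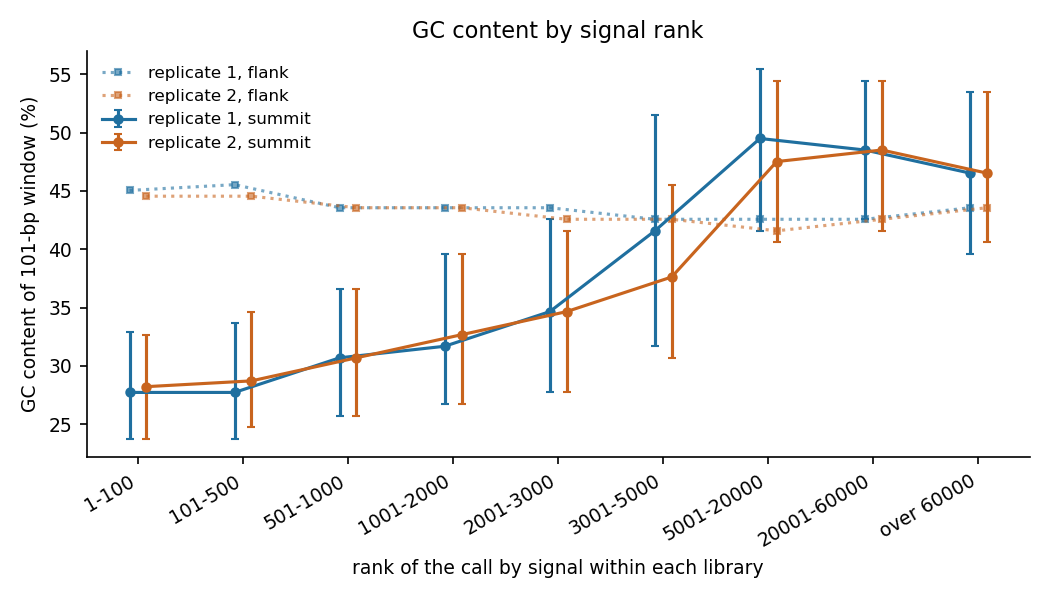
Median GC content (%) of windows at the summits (circles, bars from the lower to the upper quartile) and 500 bp to the right (squares) by signal rank within each library's ranked list, for replicate 1 (blue) and replicate 2 (orange). Summit GC rises from 27.7% and 28.2% for the 100 strongest calls to 49.5% and 47.5% for ranks 5001 to 20000, which lie beyond the thresholded lists.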

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

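Some strong calls lie outside the lists compared. On the arms, 119 calls of the joint ranked list reach the lowest score of the main list and are not in it. They include 6 of the 100 strongest joint calls, and 3 of the 119 overlap a peak of any thresholded list. The strongest is intronic, 1413 bp from the TSS of cbt (2L, positions 480920 to 481262, signal 2355), followed by calls near Lk6 (signal 1479) and larp (signal 1069). By arm, 59 lie on 3R and 27 on 2L. Their median GC content was 40.6%, against 33.7% for main-list summits. The deposited lists are already restricted by the authors' processing, and why these calls are absent was not tested. They cannot be read as binding sites that the main list missed. The genes concerned count as unbound in the report unless another summit reaches them. A further 47 main-list peaks lie on assembled sequences outside the arms and were not placed.

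Of the tests in the paragraphs that follow, those on the tagged gene and on chromosome 4 were chosen after the results were seen. Those on AT content concern a pattern that was itself examined after the main results were seen. The design has 1 group, so no biological explanation was tested against the technical ones.

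Summits were AT-rich in both libraries, and more so the stronger the peak. In sequence of 25 to 30% GC, promoters held 5.85 times (95% interval 4.73 to 7.27) as many summits per Mb as intergenic sequence in replicate 2 and 8.71 times as many in replicate 1. This speaks against AT content as all that draws calls. However, the intergenic bases included chromosomes 4 and Y, where calls of any strength were few. Masked repeats were not removed either, and how far these raise the ratio was not measured. Masked repeats were argued against as the whole cause, since among the 355 of 3012 replicate 1 and 402 of 3537 replicate 2 peaks with no masked base in either window the median summit was lower than its flank by -7.92 and -8.91 percentage points, and the other peaks were not tested for this. The upstream DNA of promoters is AT-rich in general, at a median of 36.4% GC 50 to 200 bp upstream of unbound genes. That of bound genes was lower still, by -3.97 points in each library (95% interval -4.64 to -3.31 in replicate 1) and by -3.31 points in the main list (95% interval -3.97 to -3.31). Promoter composition in general may thus account for much of the pattern at promoters, but not for all of it. A preference of the protein, of open promoter DNA in these embryos, or of the library preparation for AT-rich fragments at open sites remains open, and control DNA was not analysed here.

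The strongest site lies in the tagged gene. Extra copies raise signal only as far as the transgene reaches, and its extent and copy number are not given in the sources used here. The site had 63.8 times the median signal of the other calls within 20 kb in replicate 2 and 69.7 times in replicate 1 (the strongest call of other X windows of that width had a median of 4.11 and 4.35 times), and those calls stood at the median percentile 74.0 of X calls in replicate 2 and 83.6 in replicate 1. Neither value decides, since it is not known which of these calls the transgene covers. If it holds the whole gene, copies raise the other calls within the gene alike. The site exceeded the strongest other call with its summit in the gene 21.6 times in replicate 2 and 19.3 times in replicate 1. These are different calls: in replicate 2 a stronger peak across the gene's edge (signal 116) had its summit just outside and was not counted. The peak next to the gene was stronger still (signal 689 in replicate 2 and 621 in replicate 1, against 1361 and 1483 for the site). Copies may account for the rank of the site above the next one, whose signal at Ugalt it exceeded 1.08 times in replicate 2 and 1.09 times in replicate 1, and the share of its signal due to copies stays open.

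Chromosome 4 had no main-list peak. Removal of strong calls after thresholding is argued against, since at most 2 calls could have been removed: that many joint ranked calls on chromosome 4 reached the score of the main list, where 46.1 main-list peaks were expected. Calls of any strength were few: the ranked lists held 26 and 29 calls there, 0.0259 and 0.0426 of the number expected from unmasked length, although 29.1% of the chromosome is masked. The lack of sites is thus consistent with a step before ranking or with chromatin that gives few calls of any kind, and these cannot be separated with peak lists.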

How the results depend on the processing

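Chosen after the data were seen were the restriction to genes without a divergent partner, the removal of peaks with a signal under 20, the overlap with ranked lists, and all settings for GC content. Over 809 recomputed values of 96 results, 740 kept their side of the threshold or stayed within the stated range. Of these, 76 that passed in neither setting lay on the other side of no difference, such as the Grainyhead site (0.538, and 1.75 with the flank to the left) and non-coding exons (0.948, and 1.22 without replicate 1). The promoter excess (2.24 to 4.93 times expected), the lack of coding exon summits (0.0195 to 0.101 times), the X excess (1.20 to 1.27 times), the divergent promoter odds ratio (3.93 to 4.15) and the replicate overlap kept their direction and passed under every setting run. Counting gene bodies in place of promoters raised the lists bound more often from 3 to 9. This setting gives long genes more chances of a summit, and gene length was not controlled for. The ribosomal and insulator lists passed again and the cell cycle list did not (adjusted exact p = 0.0919), while the Hippo, Polycomb, Trithorax, ecdysone, glial and mesoderm lists passed, as did the EGFR and Ras list, which turned from below to above other genes (66.7%). With promoters, the count was 1 without replicate 1 and 3 without replicate 2, as the insulator and cell cycle lists did not pass in replicate 2 alone. With genes that have a ranked call as background, the histone list turned to 40%, since 5 of its genes remain. At summits over 500 bp from a TSS, 3 motifs were more frequent and 2 less frequent, against 7 and 4 over all summits, and DRE (0.833) and the Snail E-box (1.19) changed direction without passing. Motifs less frequent at summits numbered 7 without replicate 1 and 5 without replicate 2. The intron share turned to 1.07 with promoters of 200 bp. The replicate rho was 0.828 with summits within 100 bp. The cause of these shifts was not tested except where given. Another 27 values lost and 31 gained the threshold without a change of direction. No paired analysis was possible because there is 1 group. Depth is unknown, so its part in the 24.0% of main-list peaks that are in neither library's own list was not tested.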

Other observations

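All tests in this part were chosen after the main results were seen. Away from promoters, several long genes held many sites, a count with no test of density. Counting main-list summits more than 500 bp from any TSS, the nuclear receptor gene Hr4 (X, positions 1941940 to 2007956) held 14 in 66.0 kb, 11 of them in each library's own list. The transcription factor gene sbb (2R) held 16, with 10 in each library's list, the dioxygenase gene Tet (3L) 12, with 6 in replicate 1 and 7 in replicate 2, the kinase gene Raf (X) 11, the forkhead gene CHES-1-like (X) 11 in 27.0 kb, and the homeodomain gene hth (3R) 11 in 132 kb. The cell adhesion gene kirre (X) and CG1677 (X) held 17 each, those of kirre with 11 in each library's list. CG42594, next to the tagged gene, held 11, of which 1 was in the list of replicate 1 and 3 in that of replicate 2. The bithorax complex, the cluster of the posterior homeotic genes (3R, 16656623 to 16972236), held 19 sites where 10.6 were expected from its length (1.80 times, adjusted exact p = 0.037). It did not pass in either library alone, with 9 sites in replicate 1 (1.36 times expected, adjusted exact p = 0.652) and 8 in replicate 2 (1.08 times, adjusted exact p = 0.718). The Antennapedia complex held 14 against 11.3 (adjusted exact p = 0.371).

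Of 14 further gene families taken by name, none was bound more often than other genes and 2 were bound less often, by Fisher's exact test with Benjamini-Hochberg adjustment over the 14. At an unadjusted exact p of 0.05, 1 family passed as bound more often, the aminoacyl-tRNA synthetases. UDP-glycosyltransferases had 0 of 35 genes bound (adjusted exact p = 0.0247), and genes matching the cytochrome P450 name pattern 5 of 85 (5.88%, adjusted exact p = 0.0247). That pattern also took in Cyp1, a cyclophilin gene that is among the 5 bound, so its counts and tests are not of P450 genes only. In replicate 1 and replicate 2 alone UDP-glycosyltransferases had 0 and 1 bound and did not pass (adjusted exact p = 0.13 and 0.245). The set of the P450 name pattern had 2 and 4 and passed in replicate 1 but not in replicate 2 (adjusted exact p = 0.0225 and 0.124). Aminoacyl-tRNA synthetase genes had 11 of 32 bound (34.4%, adjusted exact p = 0.0752), led by SerRS and IleRS, and Mediator subunit genes 8 of 25 (32.0%, adjusted exact p = 0.208). Translation initiation factors had 9 of 44 (20.5%, adjusted exact p = 0.949, with 4 in replicate 1 and 6 in replicate 2) and complex I subunits 8 of 40 (adjusted exact p = 0.949).

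A hypothesis is that some short sequences beside the A and T tracts differ in frequency between promoter and distal sites. Among sequences of 7 bases with at least 3 G or C, the 3 with the smallest p at promoter summits of 2L and 2R were AACACTG, ACTATCG and AGGGATG, and at distal summits CACTGAG, CAGTGCA and GCACTGA. AACACTG and all 3 distal sequences hold CACTG on 1 strand, so the sets partly share a sequence. On 3L, 3R and X the promoter set was in 103 of 1265 promoter summits (8.14%) and 45 of 1816 distal ones (2.48%), an odds ratio of 3.49 (Fisher's exact p = 1.0e-12). The distal set was in 4.19% of promoter and 6.99% of distal summits, an odds ratio of 0.582 (Fisher's exact p = 0.00101). In replicate 1 and replicate 2 alone the odds ratios were 6.49 and 4.03 for the promoter set (largest exact p = 4.6e-12) and 0.6 and 0.681 for the distal set, which did not pass in replicate 2 (exact p = 0.0158 and 0.0545). The largest contrast was for ACTATCG, in 4.19% of promoter and 0.716% of distal summits. Unbound promoters were not compared, so the promoter set may mark promoters in general, and a sequence class of bound sites cannot be inferred from it. A class of distal sites stays open too. Such sequences had been looked at on all chromosomes before the test. AGGGATG and the distal set did not pass the adjusted threshold on 2L and 2R (adjusted exact p of 0.258, and of 0.0568, 0.208 and 1), and each set covers a small share of the sites.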
